A study of Homo sapiens with 15 samples.

How the data were processed

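RNA-seq was made from human HEK293-derived cells in 15 samples, 3 in each of 5 groups. Per the labels, Flp-In T-REx 293 cells with a Flag/HA control, Flag/HA-ZC3H7A or Flag/HA-ZC3H7B transgene were induced with doxycycline at 1 µg/mL for 24 h in 3 independent replicates. They were lysed in a hypotonic polysome buffer, and poly(A) RNA was made into libraries with a TruSeq RNA v2 kit. HEK293 cells with a control shRNA (Parental) and with a ZC3H7A knockout and an shRNA against ZC3H7B (DD) were selected with puromycin at 5 µg/mL, released 2 passages before collection, and their libraries were made by a company with another protocol. Whether the 3 samples of Parental and of DD are separate cultures is not given in the sources used here, so their p-values measure the spread between those samples. The sources also do not say whether each transgene was carried by several lines. The overexpression p-values measure the spread between the replicates of a group and not between lines.

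The deposited table holds 55773 genes by 15 libraries of normalized counts, treated here as a signal with unit size-factor-normalized reads. Per the submitters' processing notes, STAR 2.7.10b, HTSeq and DESeq2 were used with the hg19 genome, and the notes do not give the role or settings of each tool or the gene annotation. The signal values were tested: in each library 100% lay within 0.01 reads of a whole multiple of the value of a single read, so the authors had divided whole counts by a factor per library, and whole reads were recovered. Library totals were 45.5 to 57.6 M reads in the overexpression experiment and 12.2 to 15.5 M reads in the depletion experiment. The biological coefficient of variation within groups was 2.04% in the control, 8.85% with ZC3H7A, 4.34% with ZC3H7B, 10.3% in Parental and 4.81% in DD.

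Tests used log2 of the value plus a pseudocount of 1 and genes with a value of at least 10 in at least 3 libraries of the fit. A linear model was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, and genes with a Benjamini-Hochberg adjusted p under 0.05 (two-sided) were called. The 9 overexpression libraries shared a fit that gave ZC3H7A against control, ZC3H7B against control and ZC3H7A against ZC3H7B. DD against Parental was fitted apart on 6 libraries. Recovered reads were also tested with edgeR 4.0.16 and DESeq2 1.42.0. Folds of genes with 30 or fewer reads over a group are ratios of reads with 95% exact binomial intervals, and folds against a group without a read are lower bounds against a floor of 3 reads over the group. Intervals and bounds cover counting error only.

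Gene lists were fixed in advance and tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and lists with fewer than 5 tested members were only counted. Camera with an estimated correlation and fry were run beside it. The lists covered translational repression by GIGYF and 4EHP proteins, CCR4-NOT, decapping and exonuclease decay, ribosome collision, decay factors and transcripts of nonsense-mediated decay, the integrated stress response, unfolded protein and heat shock responses, interferon, NF-kappaB, immediate early, p53, cholesterol, hypoxia, G1/S, G2/M, tRNA synthetase, TGF-beta and matrix, epithelial and mesenchymal, neuronal, microRNA, CCCH, cytosolic and mitochondrial ribosomal, oxidative phosphorylation, mitochondrially encoded, ZNF, histone, long intergenic and small nucleolar RNA host genes, and markers of fibroblasts, keratin epithelium, leukocytes and endothelium. Called members are also given adjusted over the list alone.

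The genes named were chosen by a rule set in advance. It took ZC3H7A and ZC3H7B, then the 10 largest rises and 10 largest falls among called genes (5 each way between the overexpressions) with a mean of at least 100 in the higher group, no overlap between libraries and a coding or long non-coding type. It also took up to 4 members per list with the lowest adjusted p, and the 10 opposed genes with the largest smaller fold change in overexpression and DD. Some genes the rule selects are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

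Row names were matched to GENCODE 29 on GRCh38, and an hg19 annotation was not used here. Of the names, 34274 matched a current symbol, 1365 an older symbol and 20106 none, and 28 were date-like or repeated and were left out of matching. The annotation was used for gene types, sequences, chromosomes and gene order, and no coordinates are given. For 19013 genes with a complete coding sequence, the share of codons ending in A or T was taken from the longest one. Neighbouring genes with a mean of at least 100 were grouped in runs of about 40 along each chromosome, the trend of each library with transcript A+T share was removed, and run medians were compared with 100 shuffles of gene order.

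On simulated unchanged groups with planted changes, limma recovered 92% of 1.5-fold and 100% of 2-fold changes in the overexpression design with 11 false calls among 17776 genes, and 70% and 92% in the depletion design with 7 among 18512. Alternatives covered the pseudocount, the filter, the scaling (TMM, recomputed size factors, quantile), the tool, sample weights, the replicate number as a block, a smaller and a larger fit, a fold threshold and leaving out each library. Removal of the base-content trend and of run medians was added later.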

Results

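The data were RNA-seq profiles of human HEK293-derived cells, an established kidney-derived line, in 5 groups of 3 libraries each. In the overexpression experiment, Flp-In T-REx 293 cells carried a doxycycline-inducible transgene for a tagged protein. The 3 groups expressed a tag control, Flag/HA-tagged ZC3H7A or Flag/HA-tagged ZC3H7B. Both proteins belong to the CCCH zinc-finger family, whose members bind RNA. In the depletion experiment, libraries labelled Parental came from cells with a control shRNA. Libraries labelled DD came from cells with a ZC3H7A knockout and an shRNA against ZC3H7B. Library totals in the overexpression experiment, in M reads, were 57.3, 46.5 and 50.5 in the control, 45.5, 53.2 and 47.6 with ZC3H7A and 57.6, 52.5 and 53.9 with ZC3H7B. In the depletion experiment they were 13.3, 12.2 and 13.7 M reads in Parental and 15.5, 12.2 and 13.6 M reads in DD. The small non-coding RNAs RN7SK, RN7SL1, RN7SL2, RPPH1 and RMRP took 5.60% to 6.60% of the reads in Parental and DD and 0.000724% to 0.00539% in the overexpression libraries, so values were compared only within each experiment. Values below are size-factor-normalized read counts, given as mean ± SD over 3 libraries, and fold changes are log2 with the limma standard error.

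ZC3H7A and ZC3H7B were measured first in every library. The normalized count of ZC3H7A was 3180, 3374 and 3223 in the controls and 10546, 10131 and 12898 with tagged ZC3H7A (log2 fold change 1.77, SE 0.0756, limma adjusted p = 2.98e-09). ZC3H7B was 5951, 5818 and 6044 in the controls and 28082, 26712 and 26632 with tagged ZC3H7B (log2 fold change 2.19, SE 0.0473, limma adjusted p = 7.55e-11). The other gene also differed from the controls in each overexpression. ZC3H7B rose with ZC3H7A to 7976 ± 508 (log2 fold change 0.42, SE 0.0473, limma adjusted p = 5.19e-06), and ZC3H7A fell with ZC3H7B to 2032 ± 89.96 (log2 fold change -0.68, SE 0.0756, limma adjusted p = 6.91e-06). In DD, ZC3H7B was 999.8, 1168 and 1083 against 5948, 6484 and 6958 in Parental (log2 fold change -2.58, SE 0.0817, limma adjusted p = 4.19e-09). ZC3H7A was 1640, 1561 and 1771 in DD against 1585, 1528 and 1684 in Parental and did not pass the test (log2 fold change 0.05, SE 0.0770, limma adjusted p = 0.67). Gene-level reads do not show whether the knocked-out gene still made protein. In the GENCODE 29 annotation of GRCh38, ZC3H7A (ENSG00000122299) lies on chromosome 16 and ZC3H7B (ENSG00000100403) on chromosome 22.

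**Figure D1:**
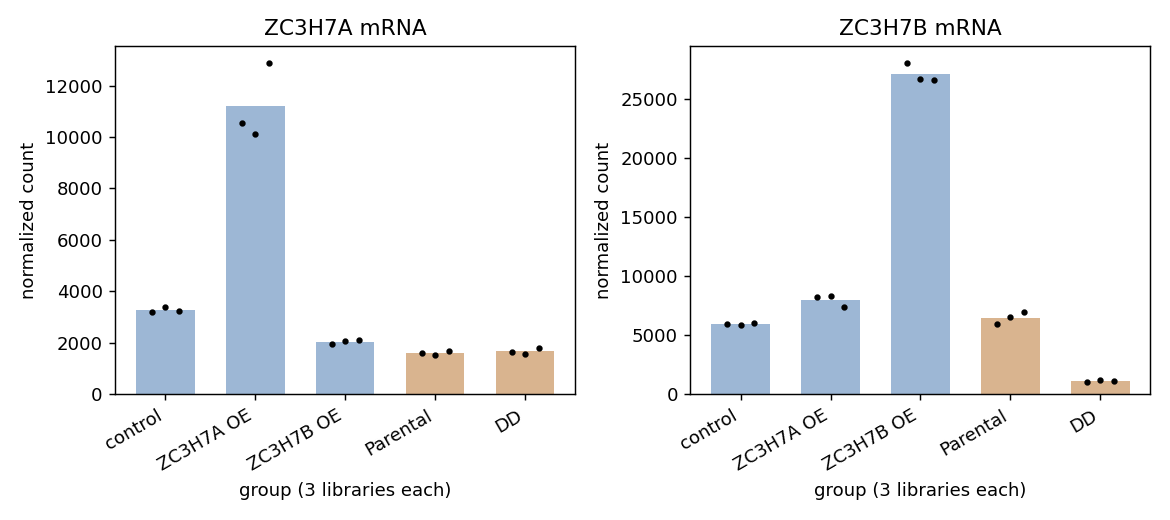
Normalized counts of ZC3H7A and ZC3H7B in the 15 libraries; bars are means of 3 libraries and points single libraries. ZC3H7A rose to a mean of 11192 with its own transgene, and ZC3H7B fell to a mean of 1084 in DD.

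The comparison of ZC3H7A with the control asked which transcripts change. Most tested members of the integrated stress response, ribosomal protein and oxidative phosphorylation lists rose, and most tested histones, interferon-stimulated genes and long intergenic RNAs fell. These list calls used camera at a preset correlation: with an estimated one, 0 of 33 lists were called and 2 had an unadjusted p under 0.05. Fry, which tests if members move one way on balance without comparing them with other genes, called 24. Of 17673 tested genes, 6135 rose and 7277 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and 710 and 1817 of them by at least 2-fold. The ZC3H7A and control libraries did not overlap in 77.9% of genes (10% by chance). The largest rises included several transcripts close to absent in the control, for which ratios of reads are given with 95% counting intervals. RPH3A, a synaptic vesicle protein, rose 1824-fold (interval 504.4 to 15064). The zinc-finger gene ZNF22 rose 388-fold (interval 151 to 1425). THNSL2, which resembles threonine synthase, rose at least 265-fold and HTRA3, a secreted protease, at least 234-fold against controls without a read. IFI16, a DNA sensor, rose 148-fold (interval 93.5 to 250.3), the sodium leak channel NALCN 147-fold (interval 81.9 to 295), the T-cell surface protein CD7 108-fold (interval 49.5 to 297) and the transmembrane reductase CYB561 68.9-fold (interval 46.5 to 107). AMOT, which binds the Hippo effector YAP, rose from 425 ± 30.2 to 9957 ± 81.4 (log2 fold change 4.55, SE 0.0506, limma adjusted p = 5.90e-14). Among the falls, MFAP2, a microfibril protein, was 1668-fold (interval 299 to 65923) lower and the GABA transporter SLC6A11 at least 289-fold lower. TENM1, a neuronal adhesion protein, fell to 27.1 ± 10.4 from 1090.0 ± 76.6 (log2 fold change -5.36, SE 0.288, limma adjusted p = 1.37e-08). LINC00958 was 39.2-fold (interval 25.5 to 63.6) lower and the scaffold gene DLGAP1 32.3-fold (interval 19.7 to 56.8) lower. IGFBP7, which binds insulin-like growth factors, fell to 23.6 from 531 (log2 fold change -4.44, SE 0.102, limma adjusted p = 4.74e-11), and P-cadherin CDH3 to 20.1 from 420.3 (log2 fold change -4.33, SE 0.112, limma adjusted p = 1.03e-10). The axonemal dynein DNAH6 (log2 fold change -3.88), LINC01021 (-3.78) and the antiviral enzyme OAS3 (-3.63) fell as well. The intervals cover counting error only.

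With ZC3H7A, the gene lists fixed in advance moved as follows. In the integrated stress response list, 23 of 30 tested members rose, 2 fell and 5 did not pass (23 and 2 adjusted over the list alone). Stress-response genes had a median log2 fold change of 0.58 (camera adjusted p = 1.24e-05, adjusted p = 0.60 with an estimated correlation). CHAC1, which breaks down glutathione, rose with a log2 fold change of 1.81 (SE 0.0854), the amino-acid transporter SLC7A5 with 1.26 (SE 0.0548), asparagine synthetase ASNS with 1.02 (SE 0.0451) and the transcription factor CEBPB with 1.39 (SE 0.0463). Of the cytosolic ribosomal proteins, 66 of 84 tested members rose, 6 fell and 12 did not pass (66 and 6 adjusted over the list alone). Cytosolic ribosomal proteins had a median log2 fold change of 0.36 (camera adjusted p = 2.10e-09, adjusted p = 0.63 with an estimated correlation). RPL22L1 rose by 2.48 (SE 0.0511), RPL35 by 1.05 (SE 0.0463) and RPL8 by 1.19 (SE 0.0520). Of the mitochondrial ribosomal proteins, 41 of 75 tested members rose, 19 fell and 15 did not pass (42 and 19 adjusted over the list alone). Mitochondrial ribosomal proteins had a median log2 fold change of 0.16 (camera adjusted p = 0.0096, adjusted p = 0.63 with an estimated correlation). MRPS12 (1.46), MRPL4 (1.251) and MRPS18A (0.78) rose, and MRPL39 fell (-0.85). Of the nuclear-encoded oxidative phosphorylation genes, 54 of 80 tested members rose, 14 fell and 12 did not pass (54 and 14 adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of 0.28 (camera adjusted p = 5.64e-05, adjusted p = 0.63 with an estimated correlation). The complex III subunits UQCRFS1 (1.01) and CYC1 (1.26) and ATP synthase subunit ATP5C1 (0.78) were among them. In the hypoxia and glycolysis list, 17 of 27 tested members rose, 6 fell and 4 did not pass (17 and 6 adjusted over the list alone). Hypoxia and glycolysis genes had a median log2 fold change of 0.33 (camera adjusted p = 0.008, adjusted p = 0.63 with an estimated correlation). NDRG1 rose by 1.53 (SE 0.0496), the glycolytic regulator PFKFB3 by 1.23 (SE 0.0473), hexokinase HK2 by 0.62 (SE 0.0440) and LDHA by 0.60 (SE 0.0443). In the G1/S list, 18 of 31 tested members rose, 4 fell and 9 did not pass (18 and 4 adjusted over the list alone). Genes of G1/S had a median log2 fold change of 0.28 (camera adjusted p = 0.0075, adjusted p = 0.63 with an estimated correlation). GINS1 (0.70), E2F1 (0.87) and MCM10 (0.71) rose. Of the replication-dependent histones, 2 of 29 tested members rose, 24 fell and 3 did not pass (2 and 24 adjusted over the list alone). Histone genes had a median log2 fold change of -1.53 (camera adjusted p = 2.07e-05, adjusted p = 0.60 with an estimated correlation). HIST1H2AG fell with a log2 fold change of -2.49 (SE 0.113), HIST2H2BE with -2.24 (SE 0.0800), HIST1H1C with -1.73 (SE 0.0828) and HIST1H2BK with -1.17 (SE 0.0558). Of the interferon-stimulated genes, 4 of 30 tested members rose, 21 fell and 5 did not pass (4 and 21 adjusted over the list alone). Interferon-stimulated genes had a median log2 fold change of -0.55 (camera adjusted p = 0.0075, adjusted p = 0.49 with an estimated correlation). SAMD9 (-3.56), IFI6 (-1.72) and HERC5 (-0.90) fell beside OAS3. Of the long intergenic RNAs, 18 of 127 tested members rose, 68 fell and 41 did not pass (17 and 68 adjusted over the list alone). Long intergenic RNAs had a median log2 fold change of -0.40 (camera adjusted p = 0.0096, adjusted p = 0.49 with an estimated correlation). LINC00665 (1.64) and LINC00493 (1.08) rose.

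The same was asked of ZC3H7B against the control. Most tested members of the integrated stress response list rose, among them the hormone FGF21, as did most tRNA synthetases, ribosomal proteins, G1/S genes and neuronal-lineage genes, and most histones and interferon-stimulated genes fell. Camera with an estimated correlation called 0 of 33 lists, 2 had an unadjusted p under 0.05, and fry called 24. Of 17673 genes, 5648 rose and 6647 fell (limma), 338 and 1389 by at least 2-fold, and 77.1% did not overlap (10% by chance). With each other scaling, edgeR and DESeq2 more rose than fell (TMM: 6340 and 5911). ERVMER34-1, an envelope gene of retroviral origin, rose 39.8-fold (interval 26.4 to 63.1). CGREF1, a secreted growth regulator, rose from 11.3 to 271 ± 13.8 (log2 fold change 4.48, SE 0.129, limma adjusted p = 4.32e-10). FGF21, a hormone of the starvation response, rose from 7.46 to 127 ± 12.2 (log2 fold change 3.92, SE 0.136, limma adjusted p = 2.01e-09), and INHBE, an activin subunit, from 62.5 to 515 ± 28.7 (log2 fold change 3.03, SE 0.110, limma adjusted p = 2.15e-09). ALS2CR11 (3.79), the zinc-finger gene ZNF677 (3.62), the mucin MUC16 (3.41), LINC00839 (3.01), the glycosyltransferase B3GALT1 (2.85) and the chloride channel BEST1 (2.78) were further large rises, given as log2 fold changes. TENM1 fell from 1090.0 to 5.83 ± 2.67 (log2 fold change -7.39, SE 0.288, limma adjusted p = 3.72e-09). SLC6A11 was 988-fold (interval 177 to 39063), ZNF43 103-fold (interval 62.1 to 184), DLGAP1 58.8-fold (interval 31.8 to 123.3) and ZNF502 21.1-fold (interval 14.5 to 32.1) lower. The nectin PVRL3 fell to 14.2 from 245 (log2 fold change -4.02, SE 0.106, limma adjusted p = 2.39e-10). The glycan-processing enzyme MANEA fell with a log2 fold change of -2.57 (SE 0.163), the glutathione enzyme GGT1 of -2.54 (SE 0.107), the mannosyltransferase TMTC3 of -2.42 (SE 0.146) and the coagulation inhibitor TFPI of -2.41 (SE 0.103).

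With ZC3H7B, the integrated stress response list changed in 29 genes: 26 of 30 tested members rose, 3 fell and 1 did not pass (26 and 3 adjusted over the list alone). Stress-response genes had a median log2 fold change of 0.60 (camera adjusted p = 1.84e-08, adjusted p = 0.34 with an estimated correlation). CHAC1 rose by 1.96 (SE 0.0854), CEBPB by 1.10 (SE 0.0463) and ASNS by 1.05 (SE 0.0451). For the tRNA synthetases, which charge tRNAs with amino acids, 14 of 20 tested members rose, 1 fell and 5 did not pass (14 and 1 adjusted over the list alone). The tRNA synthetases had a median log2 fold change of 0.32 (camera adjusted p = 1.36e-04, adjusted p = 0.34 with an estimated correlation). WARS rose by 1.01 (SE 0.0434), CARS by 1.00 (SE 0.0471), YARS by 0.86 (SE 0.0468) and GARS by 0.70 (SE 0.0359). With ZC3H7A, 12 rose and 6 fell of 20 (12 and 6 adjusted over the list alone; camera adjusted p = 0.11), and the list was called there once the trend with transcript base content was removed (adjusted p = 0.021). For the cytosolic ribosomal proteins, 68 of 84 tested members rose, 5 fell and 11 did not pass (68 and 5 adjusted over the list alone). Cytosolic ribosomal proteins had a median log2 fold change of 0.35 (camera adjusted p = 5.78e-12, adjusted p = 0.34 with an estimated correlation). RPL28 (0.94) and RPL36 (0.93) rose. For the mitochondrial ribosomal proteins, 46 of 75 tested members rose, 9 fell and 20 did not pass (46 and 10 adjusted over the list alone). Mitochondrial ribosomal proteins had a median log2 fold change of 0.25 (camera adjusted p = 3.63e-05, adjusted p = 0.34 with an estimated correlation). MRPL54 (1.05), MRPL4 (1.00) and MRPL34 (0.85) rose. For oxidative phosphorylation, 56 of 80 tested members rose, 7 fell and 17 did not pass (56 and 7 adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of 0.23 (camera adjusted p = 5.15e-07, adjusted p = 0.34 with an estimated correlation), with ATP5SL (0.91) and NDUFS7 (0.86) among the rises. For the G1/S list, 26 of 31 tested members rose, 3 fell and 2 did not pass (27 and 3 adjusted over the list alone). Genes of G1/S had a median log2 fold change of 0.46 (camera adjusted p = 2.54e-07, adjusted p = 0.34 with an estimated correlation). GINS1 (0.85), MCM10 (0.81), E2F1 (0.79) and UNG (0.66) rose. For hypoxia and glycolysis, 17 of 27 tested members rose, 5 fell and 5 did not pass (17 and 6 adjusted over the list alone). Hypoxia and glycolysis genes had a median log2 fold change of 0.35 (camera adjusted p = 0.0052, adjusted p = 0.34 with an estimated correlation). PFKFB3 (0.92), NDRG1 (0.90), ENO2 (0.54) and GAPDH (0.58) rose. For the neuronal-lineage genes, which HEK293 cells express, 13 of 21 tested members rose, 3 fell and 5 did not pass (13 and 3 adjusted over the list alone). Neuronal-lineage genes had a median log2 fold change of 0.46 (camera adjusted p = 0.0073, adjusted p = 0.34 with an estimated correlation). INA rose by 1.45 (SE 0.0401), CHGB by 1.12 (SE 0.0711), DPYSL3 by 0.81 (SE 0.0444) and UCHL1 by 0.70 (SE 0.0447). With ZC3H7A, 10 rose and 6 fell of 21 (10 and 6 adjusted over the list alone; camera adjusted p = 0.19), and between the overexpressions, 6 rose and 10 fell of 21 (6 and 10 adjusted over the list alone; camera adjusted p = 0.26), with a median below and a mean above 0. For the histones, 2 of 29 tested members rose, 23 fell and 4 did not pass (2 and 24 adjusted over the list alone). Histone genes had a median log2 fold change of -1.13 (camera adjusted p = 5.59e-05, adjusted p = 0.34 with an estimated correlation). HIST2H2BE (-1.92), HIST1H1C (-1.38) and HIST1H2BN (-1.46) fell. For the interferon-stimulated genes, 2 of 30 tested members rose, 23 fell and 5 did not pass (2 and 23 adjusted over the list alone). Interferon-stimulated genes had a median log2 fold change of -0.45 (camera adjusted p = 0.0017, adjusted p = 0.34 with an estimated correlation). SAMD9 (-2.12), IFITM2 (-1.23), IFI6 (-0.84) and BST2 (-0.82) fell. For the small nucleolar RNA host genes, 8 of 15 tested members rose, 2 fell and 5 did not pass (8 and 2 adjusted over the list alone). Small nucleolar RNA host genes had a median log2 fold change of 0.18 (camera adjusted p = 0.037, adjusted p = 0.34 with an estimated correlation), and the call was lost once the trend with transcript base content was removed (adjusted p = 0.15). ZFAS1 (0.69), SNHG17 (0.59) and SNHG5 (0.62) rose, and with ZC3H7A 8 rose and 6 fell of 15 (8 and 6 adjusted over the list alone; camera adjusted p = 0.63). For the long intergenic RNAs, 19 of 127 tested members rose, 61 fell and 47 did not pass (19 and 60 adjusted over the list alone). Long intergenic RNAs had a median log2 fold change of -0.30 (camera adjusted p = 0.049, adjusted p = 0.34 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.054), without control replicate 3 (0.059) and without ZC3H7B replicate 2 (0.056).

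The remaining lists were not called by camera in either overexpression. Of the translational repression genes around GIGYF proteins, 7 rose and 8 fell of 19 (7 and 8 adjusted over the list alone; camera adjusted p = 0.94) with ZC3H7A and 8 rose and 6 fell of 19 (8 and 6 adjusted over the list alone; camera adjusted p = 0.63) with ZC3H7B. AGO2 rose with ZC3H7A (1.13) and GIGYF2 fell (-0.49), while EIF4E2 rose with ZC3H7B (0.42) and AGO3 fell (-0.82). In the CCR4-NOT list, the deadenylase machinery, 7 rose and 12 fell of 22 (7 and 12 adjusted over the list alone; camera adjusted p = 0.49) with ZC3H7A and 6 rose and 8 fell of 22 (6 and 8 adjusted over the list alone; camera adjusted p = 0.99) with ZC3H7B. CNOT3 rose in both (0.94 and 0.88). In the decapping and exonuclease list, 20 rose and 9 fell of 34 (20 and 9 adjusted over the list alone; camera adjusted p = 0.19) with ZC3H7A and 19 rose and 7 fell of 34 (19 and 7 adjusted over the list alone; camera adjusted p = 0.054) with ZC3H7B. LSM4 rose in both (0.84 and 0.86). Among ribosome collision genes, 9 rose and 6 fell of 18 (9 and 6 adjusted over the list alone; camera adjusted p = 0.68) with ZC3H7A and 10 rose and 5 fell of 18 (10 and 5 adjusted over the list alone; camera adjusted p = 0.20) with ZC3H7B. The ligase LTN1 fell in both (-1.74 and -1.02). Among nonsense-mediated decay factors, 9 rose and 6 fell of 16 (9 and 6 adjusted over the list alone; camera adjusted p = 0.44) with ZC3H7A and 8 rose and 4 fell of 16 (8 and 4 adjusted over the list alone; camera adjusted p = 0.12) with ZC3H7B. Transcripts sensitive to that decay gave 9 rises and 9 falls among 20 genes (9 and 9 adjusted over the list alone; camera adjusted p = 0.98) with ZC3H7A and 10 rises and 3 falls among 20 genes (10 and 3 adjusted over the list alone; camera adjusted p = 0.081) with ZC3H7B. In the unfolded protein response list, 8 rose and 10 fell of 23 (8 and 10 adjusted over the list alone; camera adjusted p = 0.85) with ZC3H7A and 6 rose and 12 fell of 23 (6 and 12 adjusted over the list alone; camera adjusted p = 0.086) with ZC3H7B. The chaperone HSP90B1 fell in both (-1.06 and -0.68). In the heat shock list, 9 rose and 4 fell of 15 (10 and 4 adjusted over the list alone; camera adjusted p = 0.19) with ZC3H7A and 7 rose and 4 fell of 15 (7 and 4 adjusted over the list alone; camera adjusted p = 0.33) with ZC3H7B. DNAJB1 rose in both (1.36 and 0.95). In the NF-kappaB list, 7 rose and 3 fell of 13 (7 and 3 adjusted over the list alone; camera adjusted p = 0.40) with ZC3H7A and 5 rose and 3 fell of 13 (5 and 3 adjusted over the list alone; camera adjusted p = 0.69) with ZC3H7B. Immediate early genes gave 14 rises and 11 falls among 28 genes (14 and 11 adjusted over the list alone; camera adjusted p = 0.49) with ZC3H7A and 15 rises and 8 falls among 28 genes (15 and 8 adjusted over the list alone; camera adjusted p = 0.20) with ZC3H7B. MYC rose with ZC3H7A (log2 fold change 1.43, SE 0.0712, limma adjusted p = 7.80e-09). In the p53 target list, 5 rose and 14 fell of 23 (5 and 14 adjusted over the list alone; camera adjusted p = 0.051) with ZC3H7A and 6 rose and 14 fell of 23 (6 and 14 adjusted over the list alone; camera adjusted p = 0.10) with ZC3H7B. ZMAT3 (-1.38 and -1.56), TP53INP1 (-1.50 and -1.51) and the cell-cycle inhibitor CDKN1A (-1.21 and -0.92) fell in both. In the cholesterol synthesis list, 11 rose and 6 fell of 23 (11 and 6 adjusted over the list alone; camera adjusted p = 0.30) with ZC3H7A and 9 rose and 10 fell of 23 (9 and 10 adjusted over the list alone; camera adjusted p = 0.84) with ZC3H7B. In the G2/M list, 17 rose and 14 fell of 34 (17 and 14 adjusted over the list alone; camera adjusted p = 0.56) with ZC3H7A and 17 rose and 10 fell of 34 (17 and 10 adjusted over the list alone; camera adjusted p = 0.086) with ZC3H7B. In the TGF-beta and matrix list, 16 rose and 6 fell of 28 (16 and 6 adjusted over the list alone; camera adjusted p = 0.13) with ZC3H7A and 14 rose and 6 fell of 28 (14 and 6 adjusted over the list alone; camera adjusted p = 0.14) with ZC3H7B. The matrix protein SPARC rose with ZC3H7A from 36.1 to 394 ± 20.7 (log2 fold change 3.42, SE 0.178, limma adjusted p = 1.08e-08). Epithelial and mesenchymal markers gave 5 rises and 7 falls among 16 genes (5 and 7 adjusted over the list alone; camera adjusted p = 0.85) with ZC3H7A and 4 rises and 5 falls among 16 genes (4 and 5 adjusted over the list alone; camera adjusted p = 0.74) with ZC3H7B, vimentin VIM rising in both (0.86 and 0.77). In the microRNA biogenesis list, 5 rose and 9 fell of 15 (5 and 9 adjusted over the list alone; camera adjusted p = 0.78) with ZC3H7A and 6 rose and 8 fell of 15 (6 and 8 adjusted over the list alone; camera adjusted p = 0.84) with ZC3H7B. In the CCCH zinc-finger list, 10 rose and 13 fell of 28 (11 and 13 adjusted over the list alone; camera adjusted p = 0.85) with ZC3H7A and 8 rose and 17 fell of 28 (8 and 17 adjusted over the list alone; camera adjusted p = 0.23) with ZC3H7B. Mitochondrially encoded mRNAs gave 1 rise and 5 falls among 13 genes (1 and 4 adjusted over the list alone; camera adjusted p = 0.49) with ZC3H7A and 0 rises and 6 falls among 13 genes (0 and 6 adjusted over the list alone; camera adjusted p = 0.20) with ZC3H7B. Among ZNF genes, 159 rose and 198 fell of 458 (160 and 200 adjusted over the list alone; camera adjusted p = 0.94) with ZC3H7A and 144 rose and 177 fell of 458 (145 and 177 adjusted over the list alone; camera adjusted p = 0.99) with ZC3H7B. Some of these lists were called by camera once the trend with transcript base content was removed. With ZC3H7A these were p53 targets (lower, adjusted p = 0.0014) and G2/M genes (higher, 0.039). With ZC3H7B they were p53 targets (lower, 0.013), G2/M genes (higher, 1.06e-05), the unfolded protein response (lower, 0.0104), decay factors and decay-sensitive transcripts (higher, both 0.0104) and decapping genes (higher, 0.020). All but the decapping genes were also called after run medians of neighbouring genes were removed. Of other cell types' markers, the fibroblast list gave 3 rises and 1 fall among 5 genes (3 and 1 adjusted over the list alone; camera adjusted p = 0.40) with ZC3H7A and 2 rises and 2 falls among 5 genes (2 and 2 adjusted over the list alone; camera adjusted p = 0.83) with ZC3H7B, and the keratin epithelium list 1 rise and 3 falls among 5 genes (1 and 3 adjusted over the list alone; camera adjusted p = 0.70) and 0 rises and 2 falls among 5 genes (0 and 2 adjusted over the list alone; camera adjusted p = 0.63). Leukocyte markers gave 3 rises and 1 fall among 4 genes (3 and 1 adjusted over the list alone) and 2 rises and 1 fall among 4 genes (2 and 1 adjusted over the list alone), and endothelial markers 1 rise and 0 falls among 2 genes (1 and 0 adjusted over the list alone) and 0 rises and 0 falls among 2 genes (0 and 0 adjusted over the list alone), both too short for a test. Median and mean differed in sign for the repression, collision, decay-factor and G2/M lists with ZC3H7A, and for the collision, NF-kappaB, epithelial and fibroblast lists with ZC3H7B, and for ZNF genes with ZC3H7A the test pointed up and the median down.

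**Figure D2:**
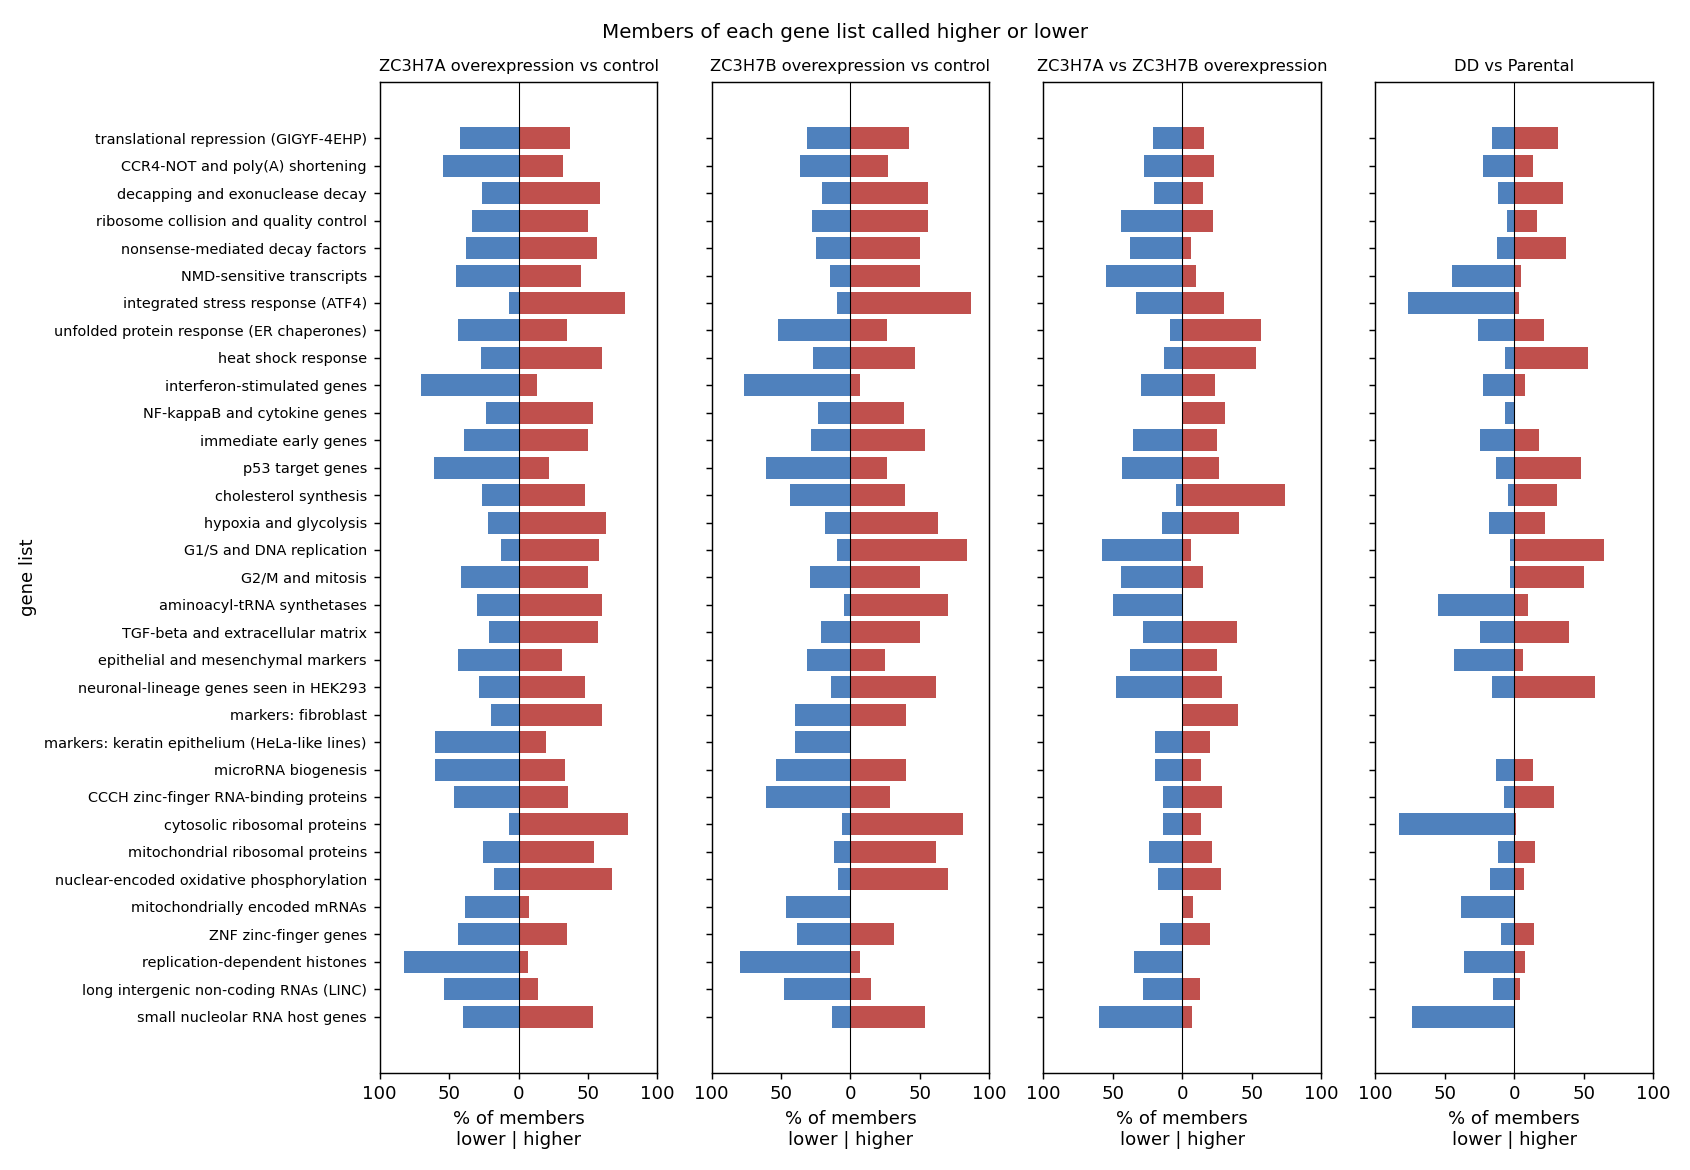
Share of tested members of each gene list called higher (right) or lower (left) in each comparison, in percent of members; lists with fewer than 5 tested members are left out. In DD 72 of 87 cytosolic ribosomal protein genes were lower, and with ZC3H7A 66 of 84 were higher.

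ZC3H7A and ZC3H7B were compared directly. Most tested genes of cholesterol synthesis and of the unfolded protein response were higher with ZC3H7A, most G1/S and small nucleolar RNA host genes were lower, and so were 10 of 20 tRNA synthetases and 10 of 29 histones. With an estimated correlation camera called 0 of 33 lists and 0 had an unadjusted p under 0.05, while fry called 21. Of 17673 genes, 4232 were higher and 3600 lower with ZC3H7A than with ZC3H7B (limma), 317 and 265 by at least 2-fold, and 49.2% did not overlap (10% by chance). More were lower by TMM (4069 against 3719), quantile scaling and edgeR, but not DESeq2. RPH3A was 3662-fold (interval 657 to 144685) higher with ZC3H7A, ZNF22 779-fold (interval 215 to 6437), THNSL2 at least 266-fold and IFI16 116-fold (interval 77.4 to 184). MFAP2 was 1261-fold (interval 226 to 49849), the poly(A)-binding protein gene PABPC4L 592-fold (interval 106 to 23399) and LINC00839 299.7-fold (interval 82.7 to 2479.9) lower. ERVMER34-1 was 134-fold (interval 61.5 to 367) and ALS2CR11 46.7-fold (interval 30.4 to 75.8) lower. For cholesterol synthesis, 17 of 23 tested members rose, 1 fell and 5 did not pass (18 and 2 adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change of 0.27 (camera adjusted p = 5.27e-04, adjusted p = 0.48 with an estimated correlation). MSMO1 (0.64) and SQLE (0.53) were higher. For the unfolded protein response, 13 of 23 tested members rose, 2 fell and 8 did not pass (14 and 2 adjusted over the list alone). Unfolded protein response genes had a median log2 fold change of 0.22 (camera adjusted p = 0.0087, adjusted p = 0.48 with an estimated correlation). HERPUD1 (0.38), PDIA3 (0.29) and PDIA6 (0.26) were higher and DERL3 lower (-0.70). For the G1/S list, 2 of 31 tested members rose, 18 fell and 11 did not pass (2 and 19 adjusted over the list alone). Genes of G1/S had a median log2 fold change of -0.16 (camera adjusted p = 4.43e-04, adjusted p = 0.48 with an estimated correlation). UNG (-0.62) and CHAF1A (-0.56) were lower and the cyclin CCND1 higher (0.53). For tRNA synthetases, 0 of 20 tested members rose, 10 fell and 10 did not pass (2 and 12 adjusted over the list alone). The tRNA synthetases had a median log2 fold change of -0.13 (camera adjusted p = 0.0086, adjusted p = 0.48 with an estimated correlation). For transcripts sensitive to nonsense-mediated decay, 2 of 20 tested members rose, 11 fell and 7 did not pass (2 and 13 adjusted over the list alone). Decay-sensitive transcripts had a median log2 fold change of -0.21 (camera adjusted p = 0.0027, adjusted p = 0.48 with an estimated correlation). SNHG12 (-0.94), GADD45B (-0.75) and GADD45A (-0.46) were lower. For the small nucleolar RNA host genes, 1 of 15 tested members rose, 9 fell and 5 did not pass (1 and 10 adjusted over the list alone). Small nucleolar RNA host genes had a median log2 fold change of -0.22 (camera adjusted p = 0.0063, adjusted p = 0.48 with an estimated correlation), SNHG3 among them (-0.80). For histones, 0 of 29 tested members rose, 10 fell and 19 did not pass (0 and 8 adjusted over the list alone). Histone genes had a median log2 fold change of -0.32 (camera adjusted p = 0.004, adjusted p = 0.48 with an estimated correlation); HIST2H2BC (-1.23) and HIST1H2AG (-0.91) were lower, and without ZC3H7A replicate 3 the list's adjusted p was 0.057. For the G2/M list, 5 of 34 tested members rose, 15 fell and 14 did not pass (5 and 17 adjusted over the list alone). Genes of G2/M had a median log2 fold change of -0.13 (camera adjusted p = 0.04, adjusted p = 0.48 with an estimated correlation). That call was lost without ZC3H7A replicate 2 (adjusted p = 0.061), ZC3H7B replicate 2 (0.072) and ZC3H7B replicate 3 (0.056). Ribosomal proteins as a list were not called, where 11 rose and 12 fell of 84 (8 and 9 adjusted over the list alone; camera adjusted p = 0.87), though RPL22L1 was higher (2.79) and its paralog RPL22 lower (-1.50). The integrated stress response list was not called either, where 9 rose and 10 fell of 30 (9 and 10 adjusted over the list alone; camera adjusted p = 0.72), and neither were interferon-stimulated genes, where 7 rose and 9 fell of 30 (7 and 9 adjusted over the list alone; camera adjusted p = 0.35). The stress-response list had a median above 0 and a mean and test below. Ribosome collision genes (adjusted p = 0.042, lower) and heat shock genes (0.041, higher) were called only after run medians of neighbouring genes were removed.

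ZC3H7A and ZC3H7B shared most of their changes. Of 17673 genes, 4662 rose and 5512 fell in both, against 1961 and 2737 if the calls were independent, and 523 were called in opposite directions against 4633. Across genes, which are not independent replicates, fold changes correlated at 0.75 (Pearson) and 0.82 (Spearman). Both comparisons used the same 3 controls, too few to split with replicates. In 20 simulated draws of unchanged groups sharing them, limma (the tool run) called 0 genes in common. The correlation was 0.50, and the covariance 0.00874 against 0.350 in the data. The draws cannot show a lasting difference of the control cells, which would enter both.

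Fold changes of neighbouring genes were compared because many named genes shared a chromosome, a step chosen after the data had been seen. Genes with a mean of at least 100 were ordered along each chromosome of GRCh38 and divided into runs of about 40 genes, after removing from each library its trend with transcript A+T share. With ZC3H7A, 38 of 293 runs had a median log2 fold change beyond 0.34, the largest in 100 shuffles of gene order, and 27 of these were higher. Chromosome 19 held 15 of the higher runs and chromosome 20 held 6, from RPS19P1 to PCMTD2 with medians of 0.47 to 0.71. The end of chromosome 8 from NSMCE2 to C8orf33 was higher by 0.64 and 0.63. On chromosome 1, 6 adjoining runs from the start of the chromosome to GMEB1 were lower, with medians of -0.57 to -0.42. Runs on chromosome 12 from TMTC3 to PTPN11 had medians of -0.58 to -0.46, and on chromosome 2 from AP1S3 to D2HGDH of -0.51 and -0.46. With ZC3H7B, 24 runs were higher and 0 lower, 14 of them on chromosome 19 and 6 on chromosome 20. The direct comparison gave 6 higher and 17 lower runs of 293, including the same runs of chromosome 1 with medians of -0.63 to -0.52. In DD, 15 of 305 runs passed, with 6 on chromosome 1 from WASH7P to XKR8 lower by medians of -0.61 to -0.38. A further 4 lower runs lay on chromosome 12 between PRR13 and CCDC53. The end of chromosome 8 was higher in DD as well, by 0.46 and 0.65. Of the genes tested in both experiments, 418 lay in runs shifted in both the ZC3H7A and the DD comparison, and 418 of them in the same direction.

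**Figure D3:**
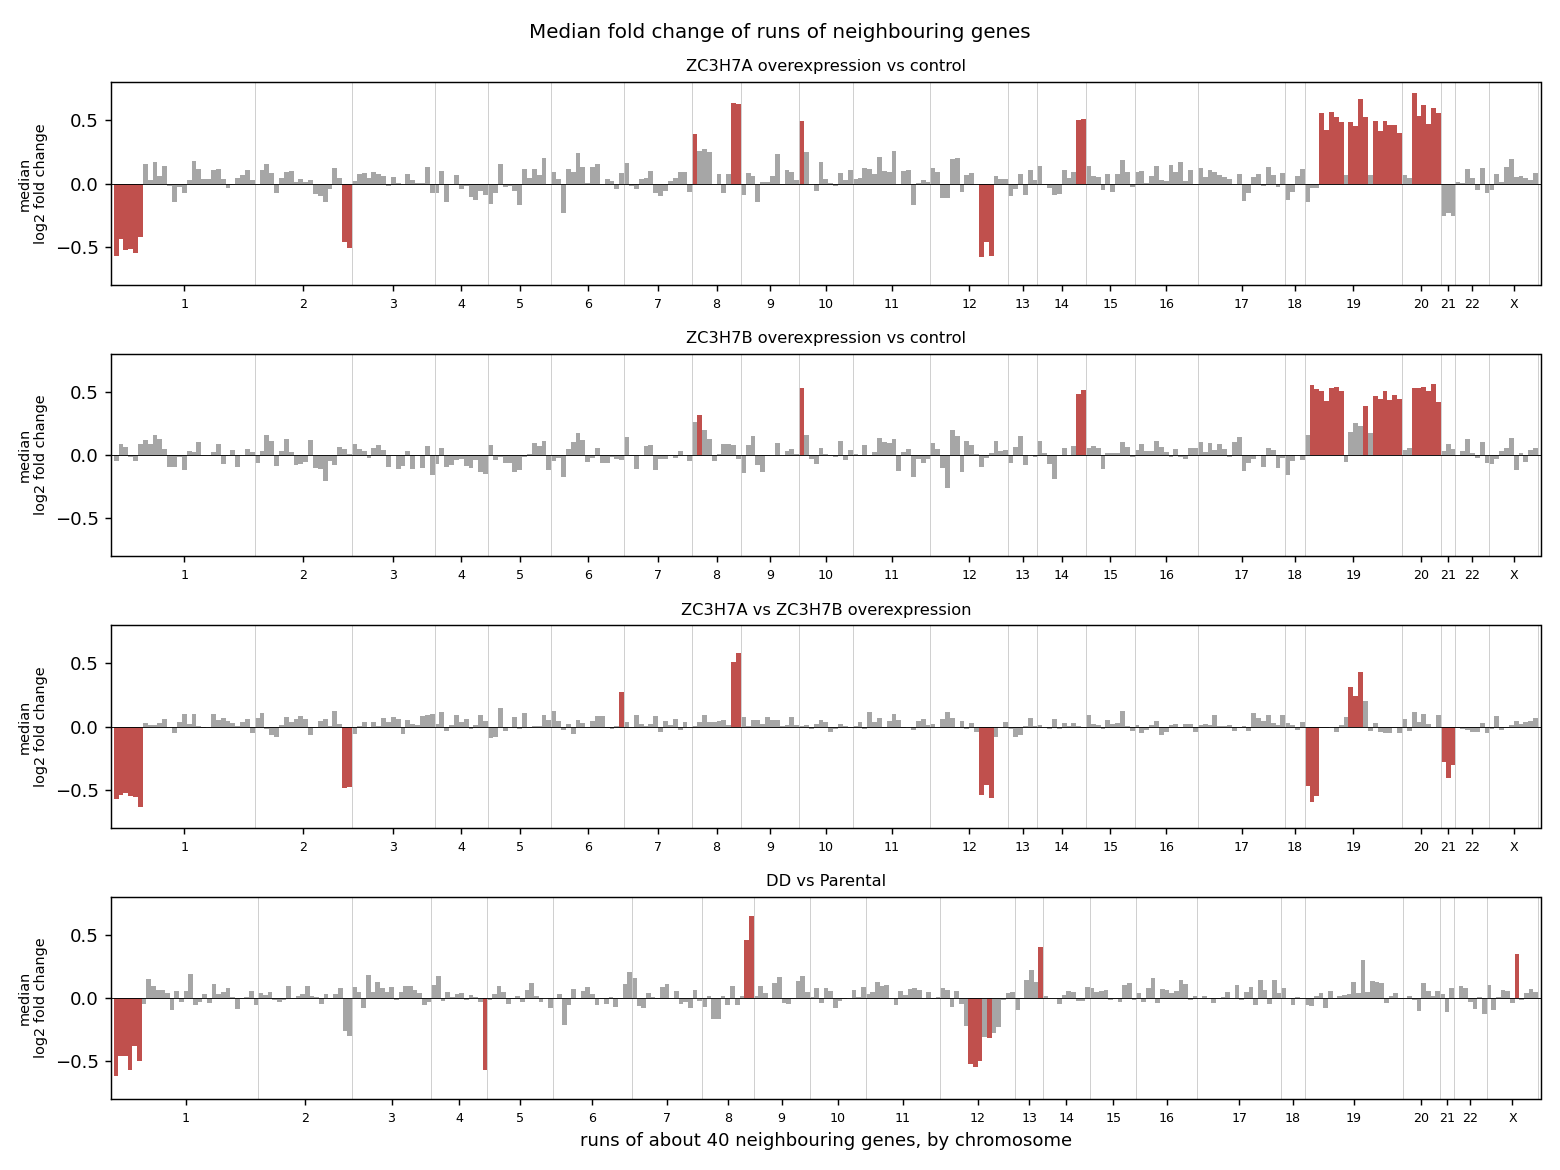
Median log2 fold change of runs of about 40 neighbouring genes along chromosomes 1 to 22 and X in the 4 comparisons, after removal of the trend with transcript A+T share; red bars lie beyond the largest median in 100 shuffles of gene order. With ZC3H7A, 38 of 293 runs did, and in DD 15 of 305.

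Several genes named above lay in such runs. With ZC3H7A these were CEBPB, E2F1, GINS1 and LINC00493 on chromosome 20, MRPS12, MRPL4, CNOT3, LSM4, DNAJB1 and LINC00665 on chromosome 19, RPL8, CYC1, NDRG1, MYC and AGO2 on chromosome 8, MCM10, PFKFB3 and ATP5C1 on chromosome 10, MFAP2 and IFI6 on chromosome 1, HSP90B1 on chromosome 12 and GIGYF2 on chromosome 2. With ZC3H7B, RPL28, RPL36, MRPL54, MRPL34, ATP5SL, FGF21, BST2, MUC16 and ZNF677 lay in shifted runs of chromosome 19, ZFAS1 and SNHG17 in those of chromosome 20 and WARS in those of chromosome 14, besides the genes of chromosomes 10, 19 and 20 listed for ZC3H7A except MRPS12 and LINC00665. SNHG3, SNHG12, RPL22 and MFAP2 on chromosome 1, GADD45B and CHAF1A on chromosome 19 and UNG on chromosome 12 did so in the direct comparison, and RPL11 and MFAP2 on chromosome 1 and RPL41, RPS26, MARS and PAN2 on chromosome 12 in DD. Once the trend and the median of each run were removed, CEBPB kept a log2 fold change of 0.34, RPL8 of 0.24, MYC of 0.59, NDRG1 of 0.67 and IFI6 of -1.54, while E2F1 was at -0.08, GIGYF2 at 0.07 and LSM4 at 0.05. With ZC3H7B, FGF21 kept 3.24 and CEBPB 0.26, while ZFAS1 was at 0.01 and SNHG17 at -0.23. In the direct comparison, UNG was then at -0.04, CHAF1A at -0.08 and RPL22 at -0.91. In DD, RPL11 kept -0.55, RPL41 -0.35 and MARS -0.25. Of the named genes called in the main test, 145 of 158 with ZC3H7A, 149 of 156 with ZC3H7B, 113 of 128 between them and 127 of 134 in DD were called in the same direction after this removal. Of the lists called by camera, 9 of 9 with ZC3H7A, 10 of 12 with ZC3H7B, 8 of 8 between them and 12 of 14 in DD kept their call and direction, where the mitochondrially encoded mRNAs, which lie in no run, could not be tested. The adjusted p of the ribosomal protein list was then 1.19e-07 with ZC3H7A, 1.35e-09 with ZC3H7B and 3.40e-21 in DD, and that of the integrated stress response list 1.26e-05, 2.49e-09 and 2.75e-11. With ZC3H7B, the small nucleolar RNA host genes (0.95) and long intergenic RNAs (0.14) lost theirs, and in DD the histones (0.0505), many of which lie together on a chromosome.

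The series title names codon dependence, and fold changes were compared with the share of codons ending in A or T in each coding sequence. In both overexpressions, genes rich in such codons were lower. Across 13592 coding genes, Spearman's rho was -0.52 with ZC3H7A (SD 0.068 over its libraries) and -0.46 with ZC3H7B (SD 0.039), where genes are not independent replicates. Genes were divided into 10 equal bands by this share. In the band with the lowest share (median 14.6%), the median log2 fold change with ZC3H7A was 0.38 and 886 genes rose and 218 fell. In the highest band (median 66.5%) it was -0.77, and 46 rose and 1186 fell. For the highest band with ZC3H7A camera gave adjusted p = 8.65e-28 (0.77 with an estimated correlation). Each of 30 codons ending in A or T had a negative rho with ZC3H7A and 29 of 30 with ZC3H7B, and within each of the 18 amino acids encoded by several codons the share ending in A or T had a negative rho. ZC3H7A itself has 64.2% of such codons and ZC3H7B 19.0%, against a median of 39.3% over genes. The direct comparison gave rho = -0.25 with an SD of 0.24 over the ZC3H7A libraries, since ZC3H7A replicate 3 gave 0.046 against -0.33 and -0.39. In DD, rho was 0.037 (SD 0.073). The A+T share of the whole transcript gave rho = -0.56 with ZC3H7A and -0.52 with ZC3H7B. Given that share, the partial rho of A/T-ending codons was -0.10 with ZC3H7A (SD 0.011 over libraries), -0.023 with ZC3H7B (SD 0.012), -0.15 between them (SD 0.034) and 0.081 in DD (SD 0.0076). Given the codons instead, that of transcript A+T share was -0.25, -0.28, 0.019 and -0.073. In 650 non-coding genes, rho with the transcript's A+T share was -0.33 and -0.29. Replicates of ZC3H7A also differed along this trend: their deviations from the group mean had a rho of -0.52, -0.55 and 0.69 with the share of A/T-ending codons, and those of ZC3H7B -0.59, 0.078 and 0.50.

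**Figure D4:**
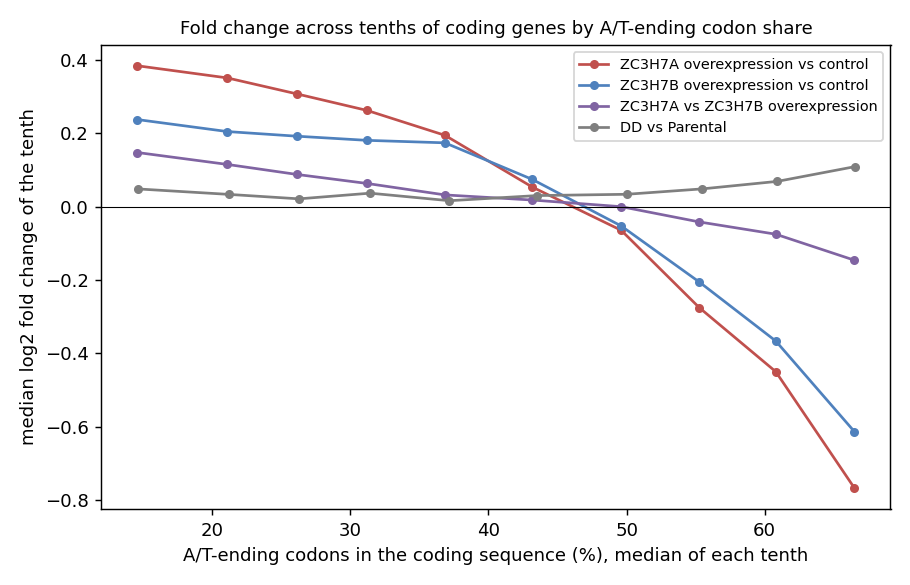
Median log2 fold change of 10 equal bands of coding genes ordered by the share of A/T-ending codons (percent) in the 4 comparisons. With ZC3H7A the medians run from 0.38 in the lowest band to -0.77 in the highest.

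DD, in which ZC3H7B reads fell and ZC3H7A reads did not, was compared with Parental. Most tested ribosomal protein genes, integrated stress response genes, tRNA synthetases and small nucleolar RNA host genes fell. Most G1/S and heat shock genes rose, as did 17 of 34 G2/M genes and 11 of 23 p53 targets. Of 31 lists, camera with an estimated correlation called 0, 4 had an unadjusted p under 0.05 there, and fry called 19. Of 18494 tested genes, 2716 rose and 2732 fell (limma), 307 and 483 of them by at least 2-fold, and 43.0% did not overlap between the groups (10% by chance). CHRDL1, a BMP antagonist, rose 68.3-fold (interval 23.1 to 334) and HDX, a homeobox gene, 71.1-fold (interval 19.3 to 592). The cancer-testis gene MAGEC1 rose 23.5-fold (interval 12.6 to 49.7), the vesicle protein SYT1 21.6-fold (interval 10.3 to 54.6), TMEM35 14.0-fold (interval 9.01 to 22.96) and DLGAP1 11.4-fold (interval 7.86 to 17.2). The exchanger SLC24A2 rose from 33.7 ± 5.36 to 387 ± 20.7 (log2 fold change 3.50, SE 0.174, limma adjusted p = 1.78e-07), the complexin CPLX2 from 24.9 ± 5.40 to 202 ± 28.1 (log2 fold change 2.98, SE 0.226, limma adjusted p = 3.20e-06) and SPARC from 149.7 ± 15.9 to 1022 ± 57.3 (log2 fold change 2.77, SE 0.113, limma adjusted p = 2.78e-08). Keratin KRT19 had no read in DD against 1282 in Parental, at least 609-fold lower. CDH3 was 941-fold (interval 168 to 37191) lower, the Ras effector RIN3 277-fold (interval 76.2 to 2292) and MFAP2 457-fold (interval 81.6 to 18103). OAS3 was 365-fold (interval 65.1 to 14465) lower, LINC00958 300.1-fold (interval 53.4 to 11897) and CYB561 186-fold (interval 33.0 to 7404). The glycosyltransferase B3GALNT1 was at least 93.2-fold lower, ERVMER34-1 at least 76.6-fold and the reductase PTGR1 146-fold (interval 25.8 to 5820.0). HDX, TMEM35 and MFAP2 lay in the shifted runs of chromosomes X and 1.

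In DD, most ribosomal protein genes were lower: 1 of 87 tested members rose, 72 fell and 14 did not pass (2 and 74 adjusted over the list alone). Cytosolic ribosomal proteins had a median log2 fold change of -0.43 (camera adjusted p = 1.36e-22, adjusted p = 0.38 with an estimated correlation). RPL13A fell with a log2 fold change of -1.23 (SE 0.0751), RPL11 of -0.99 (SE 0.0809), RPL41 of -0.92 (SE 0.0850) and RPS26 of -0.89 (SE 0.0741). In the integrated stress response list, 1 of 30 tested members rose, 23 fell and 6 did not pass (1 and 24 adjusted over the list alone). Stress-response genes had a median log2 fold change of -0.65 (camera adjusted p = 3.05e-12, adjusted p = 0.12 with an estimated correlation). ATF4 itself fell from 20009 ± 1404 to 9778 ± 73.7 (log2 fold change -1.03, SE 0.0674, limma adjusted p = 9.79e-07), and the hormone STC2 (-1.65) and the amino-acid transporters SLC7A11 (-2.41) and SLC7A1 (-1.001) fell. For the small nucleolar RNA host genes, which encode snoRNAs in their introns, 0 of 15 tested members rose, 11 fell and 4 did not pass (0 and 12 adjusted over the list alone). Small nucleolar RNA host genes had a median log2 fold change of -0.62 (camera adjusted p = 2.20e-07, adjusted p = 0.12 with an estimated correlation). SNHG3 (-1.46), ZFAS1 (-1.04), SNHG7 (-1.02) and GAS5 (-0.85) fell. Among transcripts sensitive to nonsense-mediated decay, some of which are the same genes, 1 of 20 tested members rose, 9 fell and 10 did not pass (3 and 10 adjusted over the list alone). Decay-sensitive transcripts had a median log2 fold change of -0.24 (camera adjusted p = 0.0094, adjusted p = 0.34 with an estimated correlation). Among tRNA synthetases, 2 of 20 tested members rose, 11 fell and 7 did not pass (2 and 11 adjusted over the list alone). The tRNA synthetases had a median log2 fold change of -0.24 (camera adjusted p = 0.0014, adjusted p = 0.54 with an estimated correlation). MARS (-0.82), GARS (-0.59), YARS (-0.58) and IARS (-0.57) fell. Among p53 targets, 11 of 23 tested members rose, 3 fell and 9 did not pass (12 and 3 adjusted over the list alone). Targets of p53 had a median log2 fold change of 0.28 (camera adjusted p = 2.91e-04, adjusted p = 0.12 with an estimated correlation). CDKN1A rose by 1.61 (SE 0.0698), the apoptosis gene BAX by 1.24 (SE 0.0808), PHLDA3 by 1.16 (SE 0.0743) and the repair gene DDB2 by 0.88 (SE 0.0822). In the G1/S list, 20 of 31 tested members rose, 1 fell and 10 did not pass (20 and 1 adjusted over the list alone). Genes of G1/S had a median log2 fold change of 0.43 (camera adjusted p = 5.66e-06, adjusted p = 0.44 with an estimated correlation). MCM6 (0.97) and TYMS (0.52) rose and CCND1 fell (-2.71). In the G2/M list, 17 of 34 tested members rose, 1 fell and 16 did not pass (22 and 1 adjusted over the list alone). Genes of G2/M had a median log2 fold change of 0.24 (camera adjusted p = 8.00e-06, adjusted p = 0.35 with an estimated correlation). In the heat shock list, 8 of 15 tested members rose, 1 fell and 6 did not pass (11 and 1 adjusted over the list alone). Heat shock genes had a median log2 fold change of 0.40 (camera adjusted p = 0.0023, adjusted p = 0.48 with an estimated correlation). HSPH1 (1.12) and DNAJB1 (0.77) rose and HSPB1 fell (-0.73). Among neuronal-lineage genes, 11 of 19 tested members rose, 3 fell and 5 did not pass (11 and 3 adjusted over the list alone). Neuronal-lineage genes had a median log2 fold change of 0.46 (camera adjusted p = 0.0019, adjusted p = 0.35 with an estimated correlation). CRMP1 (1.61) and INA (0.74) rose and TUBB2B fell (-0.90). Among epithelial and mesenchymal markers, 1 of 16 tested members rose, 7 fell and 8 did not pass (2 and 7 adjusted over the list alone). Epithelial and mesenchymal markers had a median log2 fold change of -0.49 (camera adjusted p = 0.0038, adjusted p = 0.34 with an estimated correlation). KRT8 (-2.84) and KRT18 (-0.83) fell, and E-cadherin CDH1 was 31.2-fold (interval 11.8 to 116) lower. Among histones, 5 of 64 tested members rose, 23 fell and 36 did not pass (5 and 27 adjusted over the list alone). Histone genes had a median log2 fold change of -0.29 (camera adjusted p = 1.80e-04, adjusted p = 0.35 with an estimated correlation). HIST1H2AL was 28.5-fold (interval 17.9 to 48.6) lower. Among oxidative phosphorylation genes, 6 of 87 tested members rose, 15 fell and 66 did not pass (4 and 12 adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of -0.07 (camera adjusted p = 0.036, adjusted p = 0.71 with an estimated correlation), and the call was lost without Parental replicate 2 (adjusted p = 0.20) and DD replicate 3 (0.21). Among mitochondrially encoded mRNAs, 0 of 13 tested members rose, 5 fell and 8 did not pass (0 and 6 adjusted over the list alone). Mitochondrially encoded mRNAs had a median log2 fold change of -0.42 (camera adjusted p = 0.019, adjusted p = 0.65 with an estimated correlation), and the call was lost without Parental replicate 1 (adjusted p = 0.12), Parental replicate 2 (0.068) and DD replicate 3 (0.10).

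The other lists were not called in DD. GIGYF-associated repression genes gave 6 rises and 3 falls among 19 genes (6 and 3 adjusted over the list alone; camera adjusted p = 0.62), CCR4-NOT genes 3 rises and 5 falls among 22 genes (3 and 5 adjusted over the list alone; camera adjusted p = 0.93) and decapping and exonuclease genes 12 rises and 4 falls among 34 genes (13 and 6 adjusted over the list alone; camera adjusted p = 0.30). PAN2 (-1.17) and DCP1A (-0.84) fell. Ribosome collision genes gave 3 rises and 1 fall among 18 genes (2 and 0 adjusted over the list alone; camera adjusted p = 0.45), and decay factors 6 rises and 2 falls among 16 genes (6 and 2 adjusted over the list alone; camera adjusted p = 0.092). The unfolded protein response list gave 5 rises and 6 falls among 23 genes (6 and 6 adjusted over the list alone; camera adjusted p = 0.62), interferon-stimulated genes 2 rises and 6 falls among 27 genes (2 and 6 adjusted over the list alone; camera adjusted p = 0.30) with a median above and a mean below 0, and NF-kappaB genes 0 rises and 1 fall among 15 genes (0 and 1 adjusted over the list alone; camera adjusted p = 0.52). Immediate early genes gave 5 rises and 7 falls among 28 genes (5 and 7 adjusted over the list alone; camera adjusted p = 0.45), and MYC fell (log2 fold change -1.298, SE 0.0820, limma adjusted p = 8.02e-07). Cholesterol synthesis gave 7 rises and 1 fall among 23 genes (7 and 1 adjusted over the list alone; camera adjusted p = 0.092), hypoxia 6 rises and 5 falls among 27 genes (7 and 7 adjusted over the list alone; camera adjusted p = 0.97) with a test below and a median above 0, and the matrix list 11 rises and 7 falls among 28 genes (11 and 9 adjusted over the list alone; camera adjusted p = 0.30). MicroRNA biogenesis gave 2 rises and 2 falls among 15 genes (2 and 2 adjusted over the list alone; camera adjusted p = 0.68), CCCH genes 8 rises and 2 falls among 28 genes (12 and 3 adjusted over the list alone; camera adjusted p = 0.11) and mitochondrial ribosomal proteins 11 rises and 9 falls among 75 genes (11 and 8 adjusted over the list alone; camera adjusted p = 0.97). ZNF genes gave 63 rises and 44 falls among 453 genes (58 and 41 adjusted over the list alone; camera adjusted p = 0.24) and long intergenic RNAs 5 rises and 18 falls among 115 genes (5 and 18 adjusted over the list alone; camera adjusted p = 0.11). Of other cell types' markers, keratin epithelium gave 0 rises and 2 falls among 4 genes (0 and 2 adjusted over the list alone), leukocyte 2 rises and 0 falls among 4 genes (2 and 0 adjusted over the list alone) and fibroblast 0 rises and 0 falls among 4 genes (0 and 0 adjusted over the list alone), and endothelial markers had no tested member.

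Overexpression and depletion were compared over 16165 genes tested in both. Most integrated stress response and ribosomal protein genes were called in opposite directions: of 30 stress-response genes, 19 were higher with ZC3H7A and lower in DD, and 21 were with ZC3H7B. Of 84 ribosomal protein genes, 58 and 63 were so, in that order. Of 31 G1/S genes, 10 were higher in both ZC3H7A and DD, 1 was higher and then lower in DD and 4 the reverse. With ZC3H7B, 16 were higher in both, 1 lower in both and 2 lower and then higher in DD. Of 29 histones (64 in DD, made by another protocol), 12 were lower in ZC3H7A and DD and 11 in ZC3H7B and DD. Shared direction within a list and effects of poly(A) selection on histone reads were not tested. Over all genes, 941 were higher with ZC3H7A and lower in DD against 942 by chance, and 934 lower and higher against 1075 (Fisher's exact test, odds ratio 0.76, p = 1.03e-09). Both rose for 1279 genes against 978 (Fisher's exact test, odds ratio 1.76, p = 5.62e-39), and both fell for 1045 against 1035 (odds ratio 1.02). With ZC3H7B, 1019 were higher and then lower in DD against 873 (odds ratio 1.34), 899 the reverse against 991, and 1107 rose in both against 906 (odds ratio 1.48). Fewer fell in both than by chance, 849 against 954 (Fisher's exact test, odds ratio 0.81, p = 2.54e-06). Without DD replicate 1 the genes sharing a direction fell to 1505 with ZC3H7A and 1226 with ZC3H7B, from 2324 and 1956. Among opposed genes, CYB561, ZNF22, RIN3 and SPINT1 (2.51 and -1.65) were higher with ZC3H7A and lower in DD, and ERVMER34-1, CGREF1 and NUPR1 (1.26 and -2.004) higher with ZC3H7B and lower in DD. DLGAP1 fell in both overexpressions and rose in DD. Chosen after the values were seen, MFAP2, LINC00958, CDH3, OAS3 and TENM1 fell and SPARC rose with ZC3H7A and in DD alike. Across genes, which are not independent replicates, fold changes in DD had a Pearson correlation of 0.14 with ZC3H7A and 0.044 with ZC3H7B.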

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

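In this part the tests of whole-transcript base content, of genes by level and of neighbouring genes were chosen after the results were seen, and the others before the data were examined.

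The effects of ZC3H7A and ZC3H7B, each against the same controls, differed by a direct test for 8 gene lists (camera adjusted p under 0.05, 0 of them with an estimated correlation; fry called 21 lists, and 0 had an unadjusted p under 0.05 with an estimated correlation). Median log2 differences, ZC3H7A over ZC3H7B, were 0.27 for cholesterol synthesis and 0.22 for the unfolded protein response. They were -0.21 for transcripts sensitive to nonsense-mediated decay, -0.22 for small nucleolar RNA host genes, -0.32 for histones, -0.16 for the G1/S list, -0.13 for the G2/M list and -0.13 for tRNA synthetases. The G2/M and histone calls were lost without some single libraries, as given above. Single genes moved in opposite directions: 235 were higher than the controls with ZC3H7A and lower with ZC3H7B, and 288 the reverse, each with a called difference. Of the genes named, ZC3H7A itself differed by 2.45 log2 units, SPARC by 4.09 and SLC24A2 by 3.02. Fitted differences of genes close to absent in a group depend on the pseudocount: MAGEC1 4.05, ERVMER34-1 -6.23 (a ratio of reads of 134-fold (interval 61.5 to 367)), ALS2CR11 -5.24 (46.7-fold (interval 30.4 to 75.8)), LINC00839 -6.51 (299.7-fold (interval 82.7 to 2479.9)) and PABPC4L -6.63 (592-fold (interval 106 to 23399)).

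The fall of genes rich in A/T-ending codons in both overexpressions was weighed first. Transcript and coding length are argued against as its cause: the partial rho given both was -0.507 with ZC3H7A and -0.438 with ZC3H7B. An effect of codon endings apart from the base content of the whole transcript stays open: given that content -0.101 (SD 0.011 over libraries) and -0.0230 (SD 0.012) were left. That met the bound written against it (under 0.5 of the trend), which was set aside after the values were seen because what was left exceeded its SD, and between the overexpressions -0.15 was left while base content given the codons had 0.019. GC bias of the libraries and an effect on the transcripts cannot be told apart: non-coding genes carried 0.596 and 0.554 of the rho of coding genes with transcript A+T share, between the bounds set for either, and replicates of ZC3H7A differed along the same trend. A dose effect of the proteins predicted an opposite trend in DD, where rho was 0.0367, less than its spread of 0.073 over libraries, and stays open, so the pattern may be technical, biological or both.

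The excess of genes that rose in overexpression and in DD was weighed second, a pattern the shared falls do not show at the called threshold (1045 against 1035 by chance with ZC3H7A, 849 against 954 with ZC3H7B), and which with ZC3H7B stands beside an excess of genes higher there and lower in DD (1019 against 873). Tests at 1.5-fold pooled rises and falls and cannot decide on rises alone. For ZC3H7A the odds ratio among genes of highest level was 2.14 (95% interval 1.01 to 4.61), a bound barely above 1. For pooled calls that argues against switching of low-level genes between cultures as the whole cause. For ZC3H7B the ratio was 0.819 (0.324 to 2.06), which goes with switching but leaves a wide range. With trend and run medians removed, ratios were 3.57 and 1.77, and shared rises 142 and 75 (251 and 139 before), so shifts of neighbouring genes stay open. A lasting difference between the cell lines used, apart from the proteins, could leave such a pattern, and no design feature separates it from an effect of the proteins.

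The 6 libraries of a comparison can be split into groups of 3 in 10 ways, the real one included, too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, called as many genes by limma: 13412 for ZC3H7A, 12295 for ZC3H7B, 7832 between them and 5448 in DD. The highest other split called 0 genes, with up to 256, 146, 3283 and 1071 at an unadjusted p under 0.05; edgeR and DESeq2 were not run on these splits.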

How the results depend on the processing

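In this part removal of the transcript A+T trend and of run medians, the partial rho given transcript A+T share, and leaving out libraries for lists and overlaps were chosen after the results were seen.

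Call counts stayed within 1.5 times under the other scalings, filters, pseudocounts, edgeR (13350 with ZC3H7A, 12413 with ZC3H7B, 7705 between them, 5479 in DD), DESeq2 (12729, 11667, 7130 and 4469), sample weights, smaller and larger fits and removal of the trend and run medians (11131, 10567, 8289 and 5118). Of the last, 1528, 1134, 148 and 23 had the opposite sign. A fold of at least 2 left 2527, 1727, 582 and 790 genes, and 1.5-fold left 3787 shared by the overexpressions, 282 opposed and 555 alike for ZC3H7A and DD, and 258 and 353 for ZC3H7B and DD, fewer by construction. With 1 library left out, counts ran from 12637 to 13837 with ZC3H7A, 11254 to 11811 with ZC3H7B and 6348 to 9559 between them. In DD they ran from 3586 (without DD replicate 1) to 6820 (without Parental replicate 3), and the shared directions from 1505 to 3128 for ZC3H7A and 1226 to 2775 for ZC3H7B, without the same libraries; the cause was not tested.

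Camera with an estimated correlation called 0 lists in each comparison (2, 2, 0 and 4 at an unadjusted p under 0.05), and fry 24, 24, 21 and 19. The Spearman correlation with A/T-ending codons was -0.606 with ZC3H7A and -0.539 with ZC3H7B at a minimum value of 100, -0.261 and -0.167 given coding length and 3' UTR GC content, and -0.101 and -0.0230 given transcript A+T share; the cause was not tested. In DD it ran from -0.0264 without Parental replicate 3 to 0.112 without Parental replicate 1.

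The groups share replicate numbers, but in no comparison did all 3 pair the libraries: correlations of deviations between libraries of the same number were -0.065, 0.035 and -0.0067 for ZC3H7A and control, 0.0017, 0.042 and 0.025 for ZC3H7B and control, and -0.015, -0.018 and -0.050 for DD and Parental. Between ZC3H7A and ZC3H7B they were 0.13, 0.0062 and 0.30, so 1 number was not over the 0.1 set for pairing. With the number as a replicate block, 13482, 12382, 8301 and 4542 genes were called, and the long intergenic RNA list with ZC3H7B missed the threshold (adjusted p = 0.063).

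Of 12220 alternative values of named genes, 12050 kept direction and side of the threshold, 152 missed the threshold and 18 changed sign. MT-ND4 with ZC3H7A was at 0.040 with the A+T trend removed. With run medians removed too, by construction genes that moved with their neighbours lost that part: with ZC3H7A GIGYF2 was at 0.066, BTG1 0.55, EXOSC5 -0.014, ZFAS1 -0.35, E2F1 -0.078, SNHG11 -0.17 and SNHG17 -0.45; with ZC3H7B CANX 0.059, MSMO1 0.0097, E2F1 -0.0069 and SNHG17 -0.23; between them EXOSC4 -0.075, LSM7 0.11, DIS3L2 0.021, MVK 0.037 and DROSHA 0.042; in DD TARBP2 0.083. The list of small nucleolar RNA host genes with ZC3H7B changed direction (adjusted p = 0.95).

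In the shallower depletion libraries 70% of planted 1.5-fold changes were recovered, against 92% in the overexpression design.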

Other observations

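In this part all tests were chosen after the result was seen.

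Neighbouring genes moved together in each of the 4 comparisons. The trend of the libraries with transcript base content is argued against as the cause: once it was removed, medians of adjoining runs of genes still had a correlation of 0.691 with ZC3H7A, 0.700 (0.69987) with ZC3H7B, 0.724 between them and 0.628 in DD. Differences in gene copy number between the cells are a candidate explanation. They predict that genes of high and low level in a run shift alike, and across runs the medians of the more and the less expressed genes had correlations of 0.768, 0.681, 0.788 and 0.680 (0.68029). Regional regulation of chromatin could give the same, no DNA was measured here, and HEK293 lines are aneuploid, so clones may differ in this way whatever they express. Named genes inside shifted runs may owe part of their change to this.

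The ZC3H7A libraries were less alike than the others of the overexpression experiment. In the first principal component, which held 64.4% of the variance, ZC3H7A replicate 3 lay at -30.5 and replicates 1 and 2 at -49.3 and -47.9. In the depletion experiment Parental replicate 3 lay at -38.9 on the second component (13.1%), and the other Parental libraries at 18.5 and 18.3. Mitochondrial rRNA took 0.77% to 0.83% of reads in the overexpression libraries and 0.0084% to 0.015% in Parental and DD.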
